A study of Homo sapiens with 6 samples.

How the data were processed

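RNA-seq was analysed from HEK293FT cells, an established human embryonic kidney line. The cells had been given supernatant containing secreted ISLR or supernatant of an empty vector control for 72 h, with 3 libraries in each of the 2 groups. The groups were taken from the sample labels, and each library column was matched to its sample by the sample title. The labels do not say whether the 3 libraries of a group came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

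The deposited table lists 58884 genes after 1 blank row was left out. Its expression values are TPM (a share of transcripts corrected for gene length and scaled to one total) per gene and library, deposited by the authors, who also averaged the TPM of the 3 libraries of each group. The p-values and adjusted p-values of a comparison by the authors are in the same deposited table, and DESeq2 is named for that comparison in the name of the deposited table. Its input and settings are not given in the sources used here. HISAT2, Cufflinks and RSEM are named without role or version, with the genome build GRCh38.p10, per the submitters' processing notes. Which of them gave the TPM, and whether the counting used strand, is not given in the sources used here. The table also gives a length per gene.

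TPM adds up to nearly the same total in every library by construction (984556.67 to 987783.8 over the listed genes), so the sequencing depth is unknown and no interval for counting error can be given. A value of 0 is called "listed at 0", because 1 of 215 members of 4 lists of widely expressed genes was at 0 in at least 1 library. No read counts were used here, so no count model was run, and the test planned for TPM was used.

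Genes with at least 1 TPM in at least 3 libraries were tested (13869 genes). Values were transformed to log2(TPM + 1), and limma 3.58.1 in R 4.3.3 was fitted with group as the only term and with the trend and robust options. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold and no minimum fold. Because of the pseudocount of 1, a log2 fold understates the change of low genes. The design, the gene lists and the rule for named genes were fixed before the data were examined.

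There were 28 fixed gene lists. They were tested with limma's camera at a preset correlation between genes of 0.01, with a mean-variance trend (a setting chosen after the design was fixed), and again with an estimated correlation. Camera compares a list with all other tested genes, so its direction is relative to them. With an estimated correlation, adjusted p rose even for lists whose estimate was below the preset one. Heat shock genes (estimate -0.0126, camera adjusted p from 2.02e-07 to 0.0391) and hypoxia genes (-0.0166, 0.0443 to 0.174) were such lists. A call lost this way is therefore no sign in itself that the members vary together. Adjusted p-values of lists were taken over the 28 lists. For each list the members past the threshold were counted over all genes and adjusted over the list alone.

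The genes to be named were ISLR, then the 12 largest rises and 12 largest falls that met 3 conditions. These were an adjusted p under 0.05, a mean of at least 5 TPM in the higher group and no overlap between the groups. Up to 4 members of each list with the smallest p-value, and CCN1, CCN2, ANKRD1, YAP1, WWTR1 and FAT1, were added. Genes without a symbol were left out, which was read as having no approved symbol source in the table's description. This reading was chosen after an early list of top genes had been seen. There were 152 names shared by 1685 rows, and those genes were left out of naming. Another 27 rows had a date in place of a gene name.

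Because the median log2 fold of all tested genes was not near 0, each gene was also tested after median-of-ratios scaling of the TPM between libraries. Other alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 TPM, quantile normalization, limma without trend and robust, and a replicate block. Further ones were each library left out in turn, a minimum change of 2-fold, an adjusted p under 0.01, and the calls of the authors' deposited table. Removal of the trend with gene length or with mean expression by lowess (span 0.3), each with scaling, was added after seeing the data. A test on transcripts was not run because the rows are genes. Gene positions were taken from GENCODE release 29.

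The fit was tested on simulated data made for this comparison with 13869 genes. Of 67 genes changed by a log2 fold of 0.5, 40.3% were recovered. The share was 70.1% of 67 genes at a log2 fold of 1 and 95.5% of 66 genes at 2. There were 5 false calls among 13629 unchanged genes. The simulated genes varied independently and few were changed, whereas 6370 genes were called in the data. These shares therefore do not carry over to the real comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.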

Results

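Messenger RNA was profiled in HEK293FT cells, a fast-growing derivative of human embryonic kidney 293 cells that carries the SV40 large T antigen. ISLR is a secreted protein with leucine-rich repeats and an immunoglobulin-like domain, known as a product of stromal cells. Cells received supernatant containing ISLR (3 libraries, titled ISLR) or empty-vector supernatant (3 libraries, titled NC) for 72 h. The deposited values were TPM per gene. The depth of each library is unknown, because TPM keeps no record of it. At least 1 TPM was reached by 14059 ± 48.2 genes in the libraries labelled ISLR and by 13417 ± 52.5 in those labelled NC (mean ± SD, n = 3 each). Pearson correlations of log2 values were 0.980 to 0.984 within groups and 0.963 to 0.972 between them. No 2 libraries were identical. The first principal component held 52.6% of the variance and separated the groups.

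The transcript of ISLR itself was near 0 in the libraries labelled ISLR and high in those labelled NC. ISLR was listed at 0, 0.02 and 0 TPM in the 3 libraries labelled ISLR, and at 510.32, 555.37 and 535.06 TPM in the 3 labelled NC. The fitted log2 difference, labelled ISLR minus labelled NC, was -9.05 (95% interval -9.19 to -8.91, limma adjusted p = 9.76e-10). In GENCODE 29 on GRCh38, ISLR (ENSG00000129009.12) is a protein-coding gene on chromosome 15 at 74173671 to 74176872 on the plus strand. Its neighbour ISLR2, a related gene at 74100311 to 74138540, reached at most 0.2 TPM in any library. The other neighbour, STRA6, at 74179466 to 74212267 on the minus strand, lay between 0.32 and 0.82 TPM in the 6 libraries. For this reason groups are called by their labels throughout, and every direction given here would turn if the labels of the table were exchanged.

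The comparison between the groups covered the whole transcriptome. In the libraries labelled ISLR, genes of amino acid supply such as ASNS, SLC7A5 and SLC7A11, mitochondrially encoded mRNAs and DNA replication genes stood higher than in those labelled NC. These 3 lists were called at the preset correlation but not with an estimated one (adjusted p = 0.0995, 0.187 and 0.0995). The mitochondrially encoded rRNAs, which are not in the list, were lower (MT-RNR2 at 8831 against 12226 TPM, MT-RNR1 at 2451 against 3562 TPM). Heat shock genes such as DNAJB1 and HSPA1B, ribosomal protein genes and nuclear genes of oxidative phosphorylation stood lower, and these lists were called with both (adjusted p = 0.0391, 0.0147 and 0.0147 with an estimated correlation). Of 13869 tested genes, 6370 passed, of which 5346 were higher and 1024 lower in the libraries labelled ISLR (83.9% higher). After median-of-ratios scaling, 5370 genes passed, 2586 higher and 2784 lower (48.2% higher). The median log2 fold over all tested genes was 0.22 as deposited and 0.01 after scaling. Log2 folds below are therefore given relative to the median of 0.22, and counts are given for both scales. Adjusted p-values of single genes are from the limma fit of the deposited fold, before the median was taken off, unless scaling is named. All of the 1024 lower genes and 2586 of the higher genes were called in the same direction on both scales, and 35 changed direction. A change of at least 2-fold was seen for 312 higher and 68 lower genes as deposited, and for 126 and 128 after scaling. On the deposited scale, the only one used for this, the groups did not overlap for 56.8% of tested genes. Chance gives 10% for a single gene. Most genes shifted together on that scale (median log2 fold 0.22), so this share is no test against chance. In the authors' deposited table, 7475 genes had an adjusted p under 0.05, 4820 with a higher and 2655 with a lower mean TPM in the libraries labelled ISLR. That table itself marks 250 genes as significant, 167 higher and 83 lower, by a rule that is not given in the sources used here. Of the 6370 genes called here, 4079 had an adjusted p under 0.05 there.

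Among the largest rises was INHBA, which encodes a subunit of activin, at 27.7 ± 2.25 TPM in the libraries labelled ISLR and 4.85 ± 1.25 TPM in those labelled NC (mean ± SD, n = 3 each, adjusted p = 0.000107). PDE8A, a cyclic AMP phosphodiesterase, stood at 32.0 ± 3.13 against 6.22 ± 0.891 TPM (adjusted p = 5.51e-05). FADD, an adaptor of death receptors, stood at 11.6 ± 1.16 against 2.23 ± 0.768 TPM. G0S2, an inhibitor of the lipase ATGL, stood at 41.4 ± 3.39 against 11.5 ± 0.69 TPM. The relative log2 folds of these 4 genes were 2.10, 1.98, 1.78 and 1.54. TMEM177 (1.46), CYP2R1 (1.43), LRCH3 (1.43), PLAGL2 (1.43) and MED1 (1.39) followed, together with NPIPB4 (1.85), RN7SL731P (1.70) and SCARNA12 (1.48). NPIPB4 belongs to a family of near-identical copies and RN7SL731P is a pseudogene of 7SL RNA, so reads of related copies could not be told apart. PDE8A, RN7SL731P, SCARNA12 and LRCH3 did not have an adjusted p under 0.05 in the authors' deposited table.

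Among the largest falls after ISLR were stress genes. HSPA6, an inducible heat shock protein, stood at 0.62 ± 0.201 TPM in the libraries labelled ISLR and 8.80 ± 0.56 TPM in those labelled NC (relative log2 fold -2.82, adjusted p = 5.22e-05). DNAJB1, a co-chaperone of HSP70, stood at 51.1 ± 1.29 against 215.4 ± 0.679 TPM (-2.27, adjusted p = 4.52e-07). FOS, an immediate early transcription factor, stood at 5.60 ± 0.342 against 17.3 ± 1.68 TPM (-1.69). HSPA1B, an inducible HSP70, stood at 199.1 ± 2.79 against 549.3 ± 8.23 TPM (-1.68), although it is nearly identical to HSPA1A and reads of the 2 genes are hard to separate. SNORA73B (-2.22), HIST2H2AC (-2.19), LIX1L-AS1 (-2.17), RPL29P14 (-2.07) and IPO9-AS1 (-1.92) also fell. SNORA73B lies within SNHG3, LIX1L-AS1 and IPO9-AS1 are antisense genes and RPL29P14 is a pseudogene. Their reads may therefore include those of the overlapping or related genes. Whether the counting used strand, which would separate antisense reads, is not given. SIRPA (-2.06) and SYT5 (-1.64) passed too, but lost the call with no filter on low values and without single libraries. The adjusted p of SIRPA was 0.127, 0.0603 or 0.125 without labelled ISLR 1, 2 or 3, and 0.111 or 0.0712 without labelled NC 1 or 3. That of SYT5 was 0.0932 or 0.0908 without labelled ISLR 2 or 3, and 0.0894 or 0.102 without labelled NC 1 or 3.

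**Figure D1:**
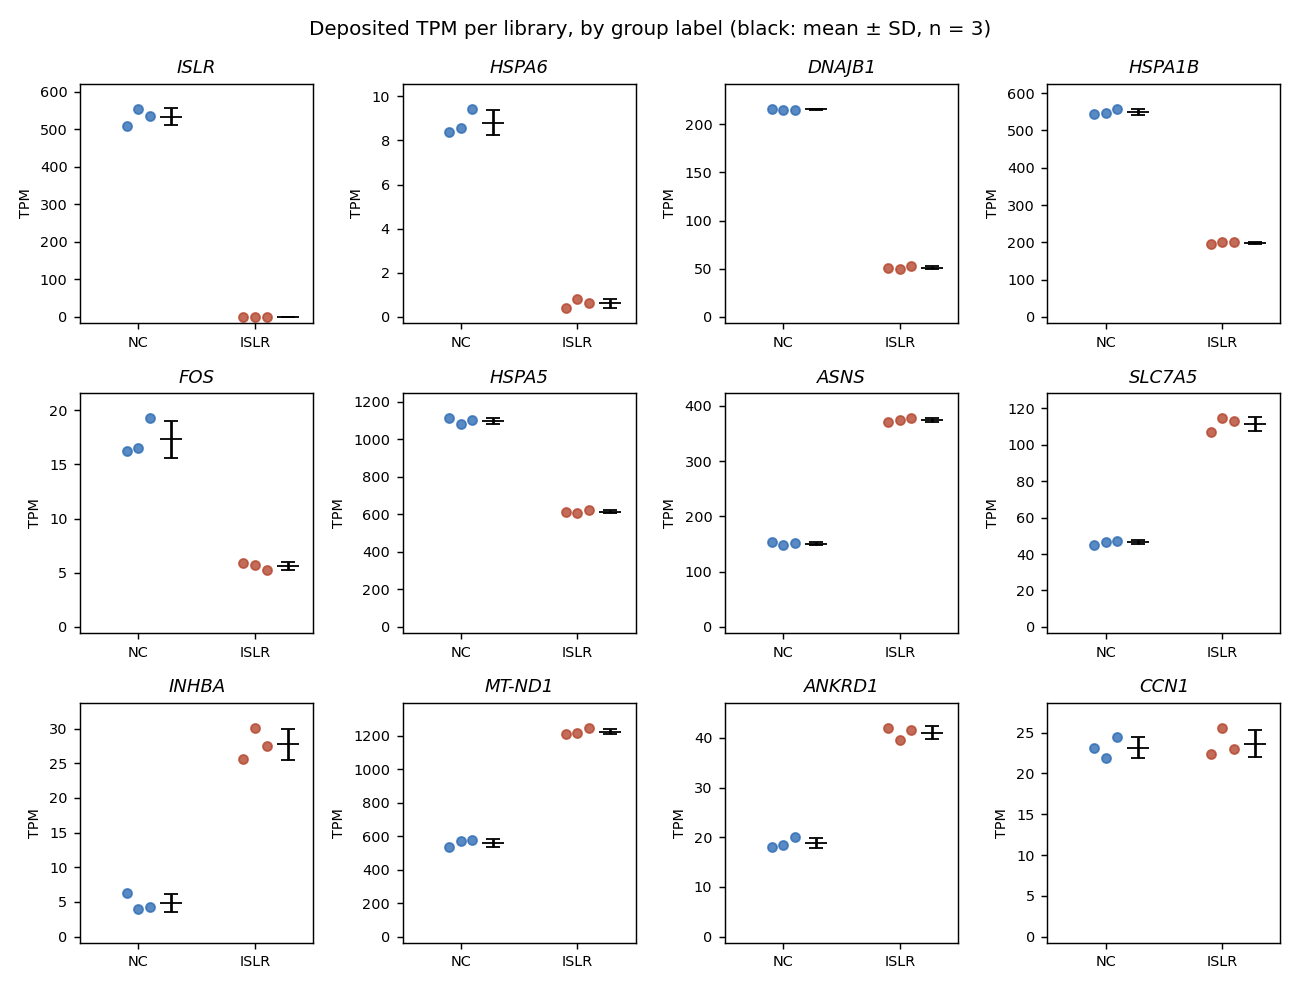
Deposited TPM (vertical axis, linear from 0) of 12 named genes in each of the 3 libraries labelled NC (blue) and the 3 labelled ISLR (red), with black bars for mean ± SD. ISLR lies at 510.32 to 555.37 TPM in the libraries labelled NC and at 0 to 0.02 in those labelled ISLR, while CCN1 overlaps between the groups.

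The study is known to have asked whether ISLR acts on Hippo signalling, the kinase pathway that restrains the coactivators YAP and TAZ, so YAP/TAZ target genes and pathway components were placed first among the lists. ANKRD1, a common YAP/TAZ target, rose from 18.8 ± 0.994 TPM in the libraries labelled NC to 41.1 ± 1.25 TPM in those labelled ISLR (relative log2 fold 0.87, adjusted p = 6.6e-05). FOXF2 (0.82) and FJX1 (0.64) rose too, and GADD45A (-0.56) fell. The 2 most used targets gave no such difference on the deposited scale: CCN1 stood at 23.6 ± 1.66 against 23.2 ± 1.27 TPM (adjusted p = 0.784) and CCN2 at 2.38 ± 0.211 against 2.35 ± 0.431 TPM (adjusted p = 0.919). After scaling, CCN1 turned to a log2 fold of -0.21 (adjusted p = 0.0498). Of 16 measured targets, 7 were higher and 1 lower (8 and 1 adjusted over the list alone), and 5 and 2 after scaling. The list did not stand apart from other genes (camera, adjusted p = 0.817).

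Of 24 measured Hippo pathway components, 11 were higher and none lower (11 and 0 adjusted over the list alone), and 6 and 3 after scaling. AMOTL1 (relative log2 fold 0.61), TAOK1 (0.55), SAV1 (0.35) and AMOT (0.19) rose, the first being an angiomotin that binds YAP and the second a kinase upstream of the core cascade. AMOT was not called after quantile normalization. WWTR1, which encodes TAZ, stood at 11.4 ± 0.77 against 11.6 ± 0.851 TPM (adjusted p = 0.818 as deposited, 0.0453 with a lower level after scaling). YAP1 stood at 8.64 ± 0.594 against 6.68 ± 0.379 TPM (adjusted p = 0.0208) and FAT1, an atypical cadherin, at 12.6 ± 2.75 against 8.48 ± 1.36 TPM (adjusted p = 0.0479). Neither passed after scaling (adjusted p = 0.326 and 0.221). Without labelled ISLR 2 or 3 or labelled NC 2 or 3, YAP1 had an adjusted p of 0.0681, 0.0611, 0.0574 and 0.0615. Without labelled ISLR 2 or 3 or labelled NC 1, 2 or 3, FAT1 had 0.131, 0.120, 0.132, 0.0879 and 0.0509. The list was not called (camera, adjusted p = 0.404), but it was with no filter on low values (0.0257).

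ATF4 target genes, which supply amino acids and their transporters under amino acid shortage, were mostly higher in the libraries labelled ISLR (23 of 26, adjusted p = 0.0995 with an estimated correlation). ASNS, asparagine synthetase, stood at 373.9 ± 3.28 against 150.6 ± 2.9 TPM (relative log2 fold 1.09, adjusted p = 1.33e-06). SLC7A5, a transporter of large neutral amino acids, stood at 111.5 ± 3.89 against 46.5 ± 1.14 TPM (1.03). PSAT1 of serine synthesis (0.98), the alanyl-tRNA synthetase AARS (0.73) and the cystine transporter SLC7A11 (1.26) rose as well. Of 26 measured members, 23 were higher and 2 lower (the same numbers adjusted over the list alone), and 19 and 2 after scaling. The 2 lower members were the transcription factors ATF4 (-0.36) and DDIT3 (-0.59), chosen for mention after their values were seen. The list was called at the preset correlation (camera, adjusted p = 3.65e-07).

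Heat shock genes of the fixed list, and less clearly unfolded protein response genes, were lower relative to other genes. The 38 DnaJ heat shock protein genes, a family formed after the data had been seen, did not share this. Of them 15 were higher and 1 lower, and 6 and 8 after scaling (camera over 14 families, adjusted p = 0.661). Of 13 measured heat shock genes, 1 was higher and 7 lower (2 and 8 adjusted over the list alone), and none and 11 after scaling. HSPA8 stood at 688 ± 12.6 TPM in the libraries labelled ISLR against 1098 ± 27.3 (relative log2 fold -0.89), and HSP90AA1 at 311.3 ± 7.97 against 378.4 ± 9.1 TPM (-0.50). The list was called (camera, adjusted p = 2.02e-07), also with an estimated correlation (adjusted p = 0.0391). Of 18 genes of the unfolded protein response, 4 were higher and 5 lower (4 and 5 adjusted over the list alone), and 2 and 10 after scaling. HSPA5, the main chaperone of the endoplasmic reticulum, stood at 613.8 ± 7.04 against 1098 ± 16.5 TPM (-1.05), HSP90B1 (-0.49) and CALR (-0.46) fell, and SYVN1, a ubiquitin ligase of protein degradation from that compartment, rose (0.33). That list was called lower than other genes (camera, adjusted p = 0.00794), with adjusted p = 0.174 with an estimated correlation, 0.0681 after quantile normalization and 0.0746 with scaling and the expression trend removed (an alternative chosen after seeing the data).

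Ribosomal protein genes fell relative to other genes, by small amounts. RPS26 (relative log2 fold -0.61), RPS9 (-0.50) and RPL24 (-0.50) were among them. Of 78 members, 2 were higher and 42 lower (2 and 46 adjusted over the list alone), and none and 76 after scaling. Their share of all TPM was 31.1 ± 0.142% in the libraries labelled ISLR and 33.1 ± 0.155% in those labelled NC (SD, n = 3 each). The list was called (camera, adjusted p = 1.04e-24), also with an estimated correlation (adjusted p = 0.0147), but quantile normalization ended the call (adjusted p = 0.0902). The median relative log2 fold of the list was -0.34 after scaling and -0.032 with the expression trend also removed (an alternative chosen after seeing the data). Over all tested genes, the median log2 fold was -0.02 for genes of 81 to 1250 nt and 0.31 for those of 5152 to 6783 nt. The median log2 ratio of mean TPM over listed genes was -0.10 for those of at least 500 TPM and 0.42 for those of 0.5 to 1 TPM.

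Nuclear genes of oxidative phosphorylation were lower relative to other genes, while 12 of 13 mitochondrially encoded ones were higher (adjusted p = 0.0147 and 0.187 with an estimated correlation). ATP5MC1, a subunit of ATP synthase, stood at 230.3 ± 13 TPM in the libraries labelled ISLR against 325.8 ± 30 (relative log2 fold -0.71). NDUFA1 (-0.53) and COX6B1 (-0.42) fell too, whereas NDUFS1 rose (0.23). Of 43 measured nuclear members, 1 was higher and 19 lower (the same adjusted over the list alone), and 1 and 38 after scaling (camera, adjusted p = 1.38e-11, and 0.0147 with an estimated correlation). Their median relative log2 fold was -0.37 after scaling and -0.13 with the expression trend also removed (an alternative chosen after seeing the data). MT-ND1 stood at 1226 ± 16.9 against 561.6 ± 24.1 TPM (0.91), MT-CO2 at 4786 ± 140 against 2655 ± 44.5 TPM (0.63), and MT-CO3 (0.51) and MT-ATP6 (0.47) rose likewise. Of the 13 mitochondrial genes, 12 were higher and none lower (the same adjusted over the list alone), and 9 and 1 after scaling (camera, adjusted p = 3.65e-07, and adjusted p = 0.187 with an estimated correlation). The share of mitochondrial rRNA went down instead, at 1.14 ± 0.0324% of TPM against 1.60 ± 0.0397%.

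**Figure D2:**
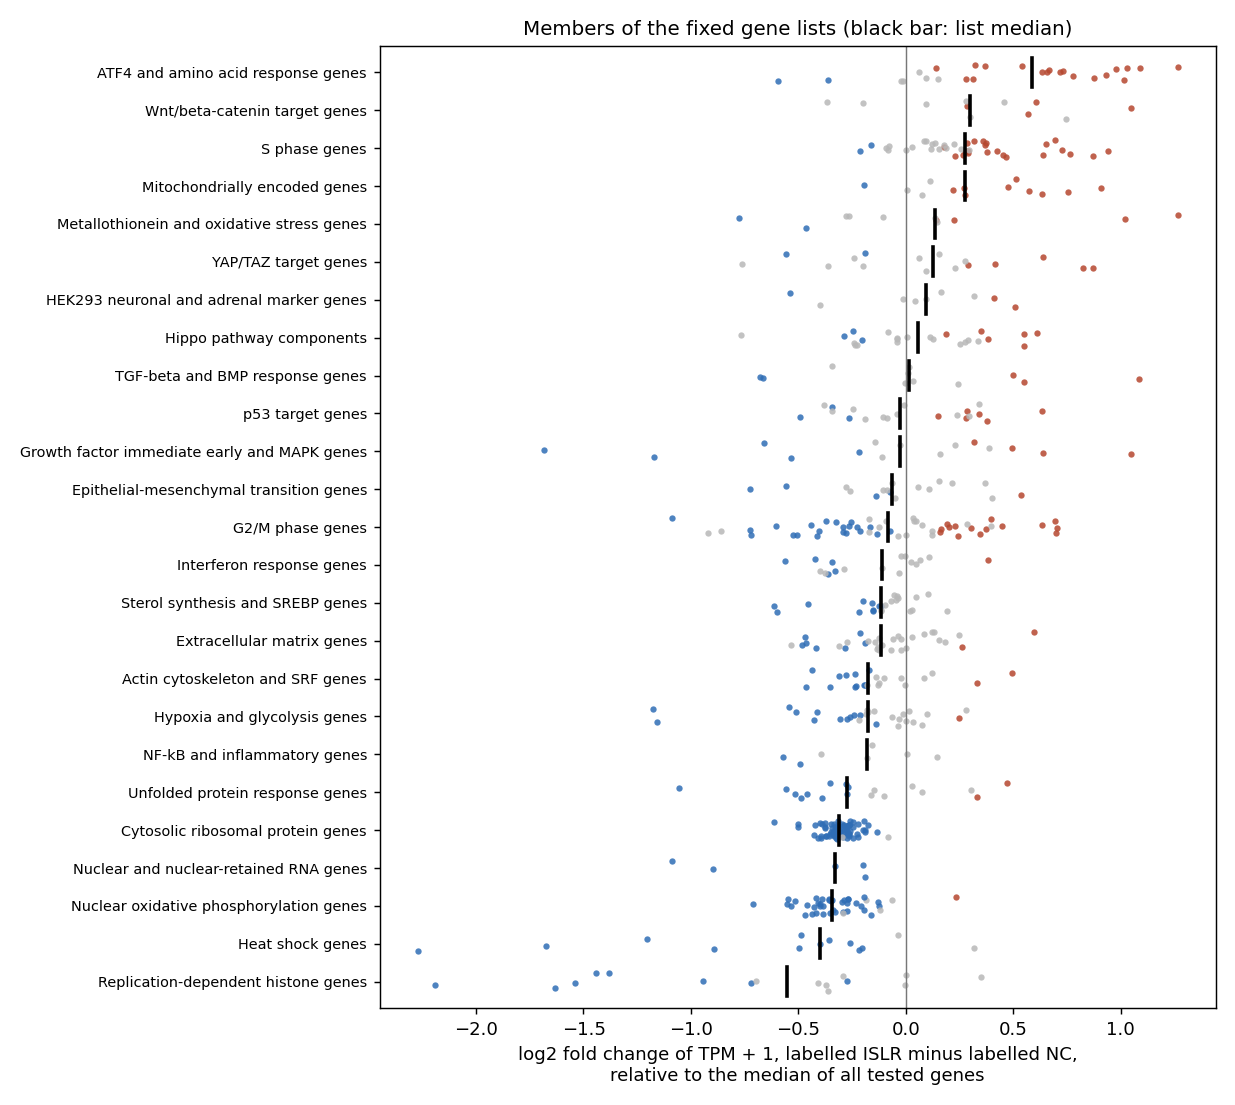
Log2 fold change of TPM + 1 (labelled ISLR minus labelled NC) relative to the median of all tested genes for members of the fixed lists with at least 5 measured genes. Each point is a gene, red (higher) or blue (lower) where it passed after scaling and grey otherwise, and black bars are list medians, which run from -0.55 for histone genes to 0.59 for ATF4 and amino acid response genes.

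Most genes of S phase were higher (36 of 41, adjusted p = 0.0995 with an estimated correlation). DTL, part of a ubiquitin ligase acting in replication, stood at 69.0 ± 3.56 TPM in the libraries labelled ISLR against 34.4 ± 2.23 (relative log2 fold 0.77, adjusted p = 0.000107). MCM6 of the replicative helicase (0.43), FEN1 (0.36) and PCNA (0.18) rose too. Of 41 members, 36 were higher and none lower (37 and 0 adjusted over the list alone), and 23 and 2 after scaling (camera, adjusted p = 1.16e-07). Replication-dependent histone genes went the other way, with none higher and 6 lower of 16 (the same adjusted over the list alone), and none and 8 after scaling. HIST1H3H stood at 2.11 ± 0.18 against 7.28 ± 0.408 TPM (-1.63), and HIST2H2BE (-1.44), HIST1H2BD (-1.38) and HIST1H1C (-0.94) fell. That list was called (camera, adjusted p = 2.02e-06), with adjusted p = 0.151 with an estimated correlation. Most such histone mRNAs lack a poly(A) tail. G2/M genes went both ways, with 24 higher and 10 lower of 52 as deposited, and 15 and 21 after scaling (camera, adjusted p = 0.806). TACC3 (0.45) rose and CKS2 (-0.60) fell.

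The nuclear RNA list and the hypoxia list were lower relative to other genes at the preset correlation. With an estimated correlation, camera gave adjusted p = 0.137 and 0.174. MALAT1, a nuclear long non-coding RNA, stood at 154.7 ± 8.41 TPM in the libraries labelled ISLR against 249.2 ± 21.4 (relative log2 fold -0.90), and SNHG1 at 643.8 ± 6.24 against 1177 ± 39.1 TPM (-1.09). Of 5 measured members of the nuclear RNA list, none was higher and 2 were lower, MALAT1 and SNHG1, and none and 5 after scaling. That list was called at the preset correlation (camera, adjusted p = 0.00392), with adjusted p = 0.137 with an estimated correlation. Where its members lie in the cell was not measured. OIP5-AS1 and GAS5 were not called as deposited (limma adjusted p = 0.394 and 0.425). SNHG1 is also counted among the small nucleolar RNA host genes given further below, so those results overlap. Quantile normalization gave adjusted p = 0.0681, and scaling with the expression trend removed gave 0.0644. Of 28 hypoxia and glycolysis genes, 7 were higher and 5 lower, and 1 and 12 after scaling. ADM (-1.16), ANKRD37 (-1.18) and the glycolytic enzyme ALDOA (-0.51) fell and PFKFB3 (0.25) rose. This list was called (camera, adjusted p = 0.0443), with adjusted p = 0.174 with an estimated correlation. The call ended without labelled ISLR 1 or 2 or labelled NC 2 or 3 (adjusted p = 0.0513, 0.0661, 0.0667 and 0.0599), with no filter (0.232), after quantile normalization (0.148), with limma without trend and robust (0.0624) and with scaling and the expression trend removed (0.135).

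Of 15 immediate early and MAPK genes, 7 were higher and 3 lower, and 4 and 5 after scaling (camera, adjusted p = 0.758). MYC, a growth-promoting transcription factor, rose from 32.8 ± 2.32 TPM in the libraries labelled NC to 80.4 ± 5.57 TPM in those labelled ISLR (relative log2 fold 1.05), and JUN rose (0.50), while JUNB (-1.17) fell beside FOS. Of 11 Wnt/beta-catenin targets, MYC included, 7 were higher and none lower, and 4 and 0 after scaling. CCND1 (0.29) and NOTUM (0.57), an enzyme that inactivates Wnt ligands, rose, but neither was called after quantile normalization. That list was not called as deposited (camera, adjusted p = 0.206) but was after scaling (0.0432). Of 11 TGF-beta and BMP response genes, 4 were higher and 2 lower, and 3 and 2 after scaling (camera, adjusted p = 0.956). SKI (1.08) and ID4 (0.50) rose, and ID3 (-0.68) and BAMBI (-0.66) fell. Of 20 p53 targets, 8 were higher and none lower, and 6 and 3 after scaling (camera, adjusted p = 0.848), with MDM2 at 0.38 and CDKN1A at 0.15.

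Lists of sterol synthesis, oxidative stress, cell structure and immunity were not called as deposited. Of 23 sterol synthesis genes, 5 were higher and 2 lower, and none and 10 after scaling (camera, adjusted p = 0.866, and 0.00879 after scaling). FDFT1 (relative log2 fold -0.61) and MSMO1 (-0.60) fell. LSS (0.19) and SREBF2 (0.05) were called higher as deposited but not after scaling (limma adjusted p = 0.145 and 0.634). Of 22 actin and SRF genes, 4 were higher and 2 lower, and 2 and 11 after scaling (camera, adjusted p = 0.227, and 0.00493 after scaling). FLNC (0.49) and VCL (0.33) rose, and ACTG1 (-0.46) fell. Among 11 metallothionein and oxidative stress genes, 4 were higher and 2 lower on both scales (camera, adjusted p = 0.806), and SRXN1, which reduces peroxiredoxins, rose (1.02). Extracellular matrix genes (8 higher and 1 lower of 32, then 2 and 7 after scaling) had an adjusted p of 0.634. Epithelial-mesenchymal transition genes (7 and 1 of 17, then 1 and 4) had 0.806, with SNAI2 at 0.54 and SNAI1 at -0.73. Interferon response genes (2 and 1 of 17, then 1 and 5) had 0.0769, which became 0.0294 without labelled ISLR 1 and 0.00454 with the p-values of the authors' deposited table. NF-kB and inflammatory genes (1 and 1 of 7, then 0 and 2) had 0.206.

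Markers of other cell types were few. Of 12 fibroblast markers, 3 passed the filter, and the call of that list (camera, adjusted p = 0.0306, and adjusted p = 0.174 with an estimated correlation) rested on ISLR, its single called member. It ended after scaling (0.0976), after quantile normalization (0.0608), with limma without trend and robust (0.0512) and without labelled NC 1 (0.0815). COL1A1 stood at 11.5 ± 0.474 against 11.3 ± 2.72 TPM and COL3A1 at 1.58 ± 0.197 against 1.27 ± 0.0643 TPM. Of 12 blood and endothelial markers only HLA-DRA passed the filter (adjusted p of the list 0.364). Of 4 measured intestinal markers CDX2 rose (0.76), and the list had an adjusted p of 0.956. The neuronal and adrenal genes that HEK293 cells express (6 higher and none lower of 9, then 2 and 1 after scaling) had 0.542, with NES at 0.41. In the lists of TGF-beta and BMP response, p53 target, epithelial-mesenchymal transition and intestinal genes, the sign of the median or mean relative fold differed from the direction of the test, and none of these 4 was called. Adjusted over the list alone, 8 Wnt/beta-catenin targets were higher and 0 lower, 5 and 2 TGF-beta and BMP genes, 5 and 2 metallothionein and oxidative stress genes, 6 and 0 extracellular matrix genes and 7 and 0 neuronal and adrenal genes. For every other list given without such a count, it was the same as over all genes.

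**Figure D3:**
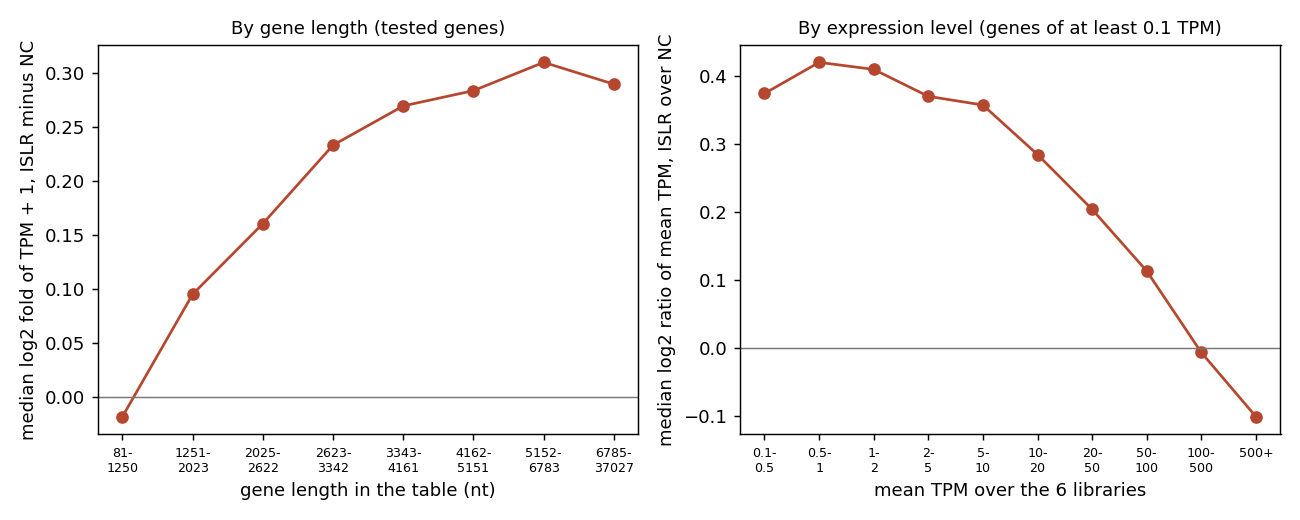
Left, median log2 fold of TPM + 1 (labelled ISLR minus labelled NC) of tested genes in 8 bins of gene length in nucleotides; right, median log2 ratio of mean TPM (labelled ISLR over labelled NC) of listed genes of at least 0.1 TPM in bins of mean TPM. The left curve goes from -0.02 for the shortest to 0.31 for genes of 5152 to 6783 nt, and the right one from 0.37 at 0.1 to 0.5 TPM through 0.42 at 0.5 to 1 TPM to -0.10 at 500 TPM and above.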

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

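The directions of change depended on scaling, and the ISLR result did not under any alternative that gave it a value. Genes higher and lower in the libraries labelled ISLR numbered 5346 and 1024 as deposited, 2586 and 2784 after median-of-ratios scaling, and 2454 and 2111 after quantile normalization. With scaling and the length trend removed they numbered 2323 and 2768, and with scaling and the expression trend removed 2413 and 2186; both removals were chosen after seeing the data. Both kinds of normalization set the median fold near 0, which by construction moves the balance. A 2-fold minimum left 380 genes (312 and 68, or 126 and 128 after scaling) and an adjusted p under 0.01 left 3883 (3342 and 541), since both are stricter. Among the tested genes, 2540 were lower in the authors' deposited table. The cause of the other changes below was not tested. The mean correlation within groups exceeded that between groups by 0.0145, which became 0.0179 and 0.0115 with pseudocounts of 0.1 and 5, 0.00712 with no filter and 0.0202 with a filter of 5 TPM. Of the 28 lists 11 were called as deposited, 13 after scaling, 14 with scaling and the length trend removed, 8 with scaling and the expression trend removed and 6 after quantile normalization. The authors' deposited table gave 12, limma without trend and robust 9, an adjusted p under 0.01 also 9, and 10 to 11 were called with 1 library left out. With an estimated correlation 3 of the 11 were called (ribosomal protein, oxidative phosphorylation and heat shock genes). The Hippo list was called with no filter (adjusted p = 0.0257; 0.0257 to 0.994 over 18 alternatives), and the YAP/TAZ list under none (0.377 to 0.995). The adjusted p ran from 2e-55 to 0.0902 for ribosomal protein genes, 4.35e-06 to 0.0746 for the unfolded protein response and 0.000123 to 0.0681 for nuclear RNAs. It ran from 8.94e-05 to 0.232 for hypoxia, 0.0432 to 0.290 for Wnt, 0.00183 to 0.996 for sterol, 0.00311 to 0.454 for actin, 0.00454 to 0.491 for interferon, 0.0257 to 0.814 for matrix and 2.62e-05 to 0.0976 for fibroblast genes. Among the 131 named genes that these alternatives covered, for those called on either scale, scaling turned the log2 fold of VIM to -0.10, GAS5 to -0.21 and CCN1 to -0.21. Scaling with the length trend removed turned SREBF2 to -0.068, VIM to -0.10, ITGB1 to -0.014 and GAS5 to -0.24. Of these 131, quantile normalization ended the call of 17 and the authors' deposited table lacked 20. With 1 library left out, 5073 to 5505 genes were called (4233 to 4665 higher, 786 to 930 lower). A replicate block gave 5778 genes (4841 higher, 937 lower) and 11 lists. Libraries with the same number hardly deviated together (r = 0.02, 0.05 and -0.06), and not every library correlated best with its own number, so the numbers were not taken as pairs. The depth of the libraries is unknown, so it could not be weighed. A test on transcripts was not run.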

Other observations

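Of 14 gene families formed from gene descriptions after the data had been seen, 5 were called by camera at the preset correlation and none with an estimated one (lowest adjusted p = 0.0886). The 9 not called were proteasome, mediator, chaperonin, kinesin, tubulin, DnaJ, initiation factor, solute carrier and ubiquitin-specific peptidase genes (adjusted p = 0.155 to 0.837). All family results are given without removal of the length or expression trend. Of 34 aminoacyl-tRNA synthetase genes, which load tRNAs with amino acids, 24 were higher and none lower in the libraries labelled ISLR, and 16 and 5 after scaling (camera over 14 families, adjusted p = 0.000197, and adjusted p = 0.0886 with an estimated correlation). IARS stood at 114.8 ± 4.28 TPM against 54.4 ± 0.553 (mean ± SD, n = 3 each), and SARS at 322.4 ± 4.17 against 217.9 ± 4.75 TPM. Of 22 nucleoporin genes 17 were higher and none lower, and 15 and 2 after scaling (adjusted p = 0.000676, and 0.0886 with an estimated correlation), with NUP62 at 43.9 ± 1.80 against 21.9 ± 1.86 TPM. Zinc finger genes had 171 higher and 8 lower of 325, and 112 and 27 after scaling (adjusted p = 0.00679, and 0.256 with an estimated correlation).

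Small nucleolar RNA host genes were lower relative to other genes, with 5 higher and 7 lower of 20, and none and 13 after scaling (camera, adjusted p = 0.000197, and 0.0886 with an estimated correlation). SNHG12 stood at 114.8 ± 7.81 TPM in the libraries labelled ISLR against 146.2 ± 2.80 and SNHG3 at 156.2 ± 3.29 against 264.2 ± 27.9 TPM. Mitochondrial ribosomal protein genes had 29 higher and 18 lower of 80, and 6 and 39 after scaling (adjusted p = 0.0192, and 0.0886 with an estimated correlation). UBB, a ubiquitin gene, fell on both scales (4014 ± 63.5 against 5009 ± 158 TPM). GAPDH also fell on both (3498 ± 44.4 against 4561 ± 88.9 TPM). Falls were common at such levels, since only 24.1% of genes of at least 500 TPM were higher in the libraries labelled ISLR. AC113410.3, which has no approved symbol, was listed at 0 in all 3 libraries labelled ISLR and at 50.25, 41.71 and 15.16 TPM in those labelled NC.

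In what follows, the 3 tests on ISLR were chosen after its levels had been seen, and both trend removals after seeing the data. The number of genes called between the groups, 6370, was set against the 9 other splits of the 6 libraries into 3 and 3, the highest of which called 1. Only 1 of the 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. Each other split mixed libraries of both groups, so the group difference raised its spread and few calls were bound to result. The contrast therefore decides nothing.

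ISLR transcript was abundant in the libraries labelled NC and near 0 in those labelled ISLR. The level of the related gene ISLR2, at most 0.13 TPM in a library labelled NC, cannot tell whether its reads were counted as ISLR. Reads moved to ISLR would leave ISLR2 low too. A single wrong label or 1 swapped pair is argued against, because the pattern held in all 6 libraries. An exchange of the 2 group labels as a whole cannot be told apart from ISLR transcript made in cells given control supernatant. All 6 libraries are affected, and the treatment was a secreted protein, so ISLR transcript of the cells is no sure check of the labels. AC113410.3 had the same pattern, listed at 0 in the libraries labelled ISLR and at 50.25, 41.71 and 15.16 TPM in those labelled NC. It does not decide the question either. If the labels were exchanged, the hypothesis would be that ISLR transcript came with the ISLR supernatant or was made from a carried-over vector, which was not tested. A response of the cells' own ISLR gene to the treatment also stays open.

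Ribosomal protein and nuclear oxidative phosphorylation genes were lower in the libraries labelled ISLR, at median relative log2 folds of -0.34 and -0.37 after scaling. With the length trend of all genes removed, they stood at -0.23 (adjusted p = 2.29e-23) and -0.25 (adjusted p = 7.26e-11), which argues against gene length as the whole cause. With the trend of fold with mean expression removed, they stood at -0.032 (camera, adjusted p = 0.0127) and -0.13 (adjusted p = 0.00048), still called. Neither list passed its bound. The bounds were set before this result was seen, though the removal itself was chosen after seeing the data. An expression trend therefore cannot be told apart from a change of these genes. Ribosomal protein genes make up 32.0% of tested genes of at least 500 TPM, so removing that trend also removes part of their own change. Oxidative phosphorylation genes make up 4.1% of them, so this hardly applies to that list. A response to the supernatants may account for what is left and stays open as a hypothesis.

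Most tested genes had a higher TPM in the libraries labelled ISLR. A lower share of the 100 most abundant and the ribosomal protein genes, which raises all other TPM, is argued against as the whole cause. Rescaled without them, the median log2 fold of the others was still 0.17, from 0.22. Other abundant genes stayed in, so a lower share of abundant genes in general cannot be told apart. Of genes of at least 500 TPM, 24.1% were higher in the libraries labelled ISLR, against 78.7% of those at 5 to 10 TPM. A background of reads spread over all genes alike is argued against by a median difference of 2.72 TPM for genes at 10 to 20 TPM against 0.403 TPM for those at 1 to 2 TPM. A difference in depth or library preparation stays open because TPM keeps no depth, as does a biological difference between the supernatants, which was not tested apart from them.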
